A study of Homo sapiens with 6 samples.

How the data were processed

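The RNA was isolated with Trizol and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols; this kit selects polyadenylated RNA and does not mark strand. The submitters' processing notes name FastQC 0.11.5, Trim Galore, cutadapt 1.10, TopHat2 2.1.0, Bowtie2 2.2.6, HTSeq 0.6.1, DESeq2 1.18.1 and the GRCh37 build, without the role or settings of each. The deposited table lists 63677 genes with their symbols, types, GRCh37 positions and 6 columns of values. The unit of these columns is a signal, gene counts that the authors divided by 1 size factor per library and rounded to 2 decimals, as the values themselves show; they are called normalized counts here. The authors also deposited a log2 fold change of high over low folate, a signed fold score made from it, and a p-value and adjusted p-value per gene. Their log2 values are far smaller than the ratios of the normalized counts and look shrunken towards 0, so they are not set beside the fold changes computed here.

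Each value is a whole multiple of its library's step within 0.01 of a read, for 100% of the values in each of the 6 libraries, so that the whole reads could be recovered. The recovered reads numbered 34344121, 32877443, 35530771, 43759528, 39385683 and 36592655 for libraries 1 to 6, and the 10 most abundant genes took 6.72% to 7.21% of them. PCR copies were not marked, so the depth does not give the number of independent molecules.

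Columns were assigned to the medium in their names, odd numbers high and even numbers low, which is the reverse of the series' design text; the values were not used to decide between them. The replicate numbers of the titles are not on the columns, so they cannot pair the libraries. Libraries with consecutive numbers were compared instead, before any fit with a block was compared with the fit without one. Over 12712 genes with a mean of at least 50 normalized counts, the deviations from the group means correlated at 0.77, 0.92 and 0.87 in the 3 pairs, and each library correlated best with its neighbour, in 1 of the 6 possible matchings. A chi-square per gene of 2.33 to 2.84 within pairs, against 15.9 to 39.5 between other libraries, exceeded counting error in every case, so no library was counted as a copy of another; this does not show that the libraries came from separate cultures. The replicate block by consecutive numbers, which calls 8 genes where the fit without it calls 0, was therefore added after seeing the data.

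The design fixed before the data were examined assumed counts and named edgeR; as the deposited values are not counts, the test it gives for that case was used. Limma 3.58.1 in R 4.3.3 was fitted with trend and robust variance to log2(value + 1), for the 18008 genes with a mean of at least 10 normalized counts in either medium, with the medium as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are high over low on that log2(value + 1) scale, which understates the change of low genes such as SNORD3A. The alternatives were edgeR 4.0.16, limma-voom and DESeq2 1.42.0 on recovered reads, other scalings and filters, pseudocounts of 0.1 and 10, and each library left out in turn. The 95% intervals come from limma, which weighs each gene's own spread between libraries with that of other genes. The weight of other genes was a median of 3.68 prior degrees of freedom without the block and 53.0 with it. The blocked intervals therefore rest mostly on pooled spread. They can be too narrow for a gene whose own pair differences vary more.

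Before the data were examined, 24 gene lists with 503 members were fixed, covering folate transport and enzymes, nucleotide and amino acid metabolism, stress responses, the cell cycle, respiration, T lineage and NOTCH genes, and markers of other cell types. All 503 members were matched, 20 of them by gene ID under an older symbol. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way and does not compare the list with other genes. The rule for named genes took any folate gene, the called genes with the largest changes and no overlap between groups, up to 4 called genes of each other list, and the 4 called genes with the smallest p. As 0 genes were called without a block, genes outside the folate lists were named because of the blocked fit, its list-alone calls or the differences between library pairs, after their values were seen. The single values of some folate genes are not reported here; they remain in the counts and ranges of their lists.

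The fits were tested on simulated reads with 200 changed genes and the depth and pair means of these libraries. All genes shared 1 dispersion of 0.00044, so genes with a larger spread were not simulated. The recovery and false calls given here may therefore be too favourable. In 17969 tested genes, limma with the block recovered 26%, 57.1%, 64% and 88% of genes changed 1.1, 1.2, 1.5 and 2-fold, with 1 false call. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Bootstrap intervals of medians used 10000 draws over genes, so they do not measure the spread between libraries. GC content and length came from GENCODE gene models of another build, matched by gene ID for 97.8% of the genes used, and no coordinates were taken from them.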

Results

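Polyadenylated RNA was sequenced from CCRF-CEM, an established human line of T-cell acute lymphoblastic leukaemia, labelled WT (wild type) in all sample titles. The cells were grown in RPMI medium with dialysed serum and either 200 nM (low) or 2 µM (high) folic acid. Each medium had 3 libraries, which the series describes as biological replicates; whether these were separate cultures, and for how long the cells were kept in each medium, is not given in the sources used here, so p-values measure the spread between these libraries. The title of the series concerns how the reliance of tumour cells on cytosolic or mitochondrial one-carbon flux depends on folate supply, and the comparison asks which transcripts differ between the media. The recovered libraries held 32877443 to 43759528 reads in genes, with 5.71% to 6.39% of them from the mitochondrial genome and 27171 to 28049 genes with at least 1 read. The labels disagree on direction: the column names give libraries 1, 3 and 5 as high and 2, 4 and 6 as low, while the design text of the series gives the odd numbers as low. Every direction here follows the column names, and all of them would turn around if the design text were right. The sample titles also give the folate as 0.2 mM and 2 mM, which is 1000 times the concentrations stated for the media.

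The abundant genes of folate transport and one-carbon metabolism had nearly the same transcript levels in both media, while the intervals of the low ones were wide. SHMT1, the cytosolic serine hydroxymethyltransferase, had 2725 ± 58.2 normalized counts in the libraries labelled high and 2633 ± 75.9 in those labelled low (mean ± SD, n = 3 each), a log2 fold change of 0.050 (95% interval -0.08 to 0.18). Its mitochondrial counterpart SHMT2 had 6993 ± 79.7 and 7061 ± 303 normalized counts, a log2 fold change of -0.013 (-0.14 to 0.11). MTHFD2, the mitochondrial methylenetetrahydrofolate dehydrogenase, stood at 7173 ± 394 and 7383 ± 338 normalized counts, a log2 fold change of -0.042 (-0.19 to 0.10). SLC19A1, the reduced folate carrier, had 3610 ± 601 and 3672 ± 672 normalized counts, a log2 fold change of -0.021 (-0.41 to 0.36). None of the 37 tested genes of the 39 in the 3 folate lists passed limma's test (smallest unadjusted p = 0.169; Benjamini-Hochberg adjusted p = 0.999976 for that gene), either over all genes or adjusted over the list alone.

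Among the 12 tested genes of folate transport and retention, 6 had a positive log2 fold change. FPGS, which adds glutamate residues to folates, had a log2 fold change of 0.030, and GGH, which removes them, of 0.064. FOLR1, the folate receptor alpha gene, had 0 reads in all 6 libraries, and the proton-coupled carrier SLC46A1 had only 15.9 ± 3.39 and 16.1 ± 3.04 normalized counts. Among the 12 cytosolic enzymes, 6 lay above 0, with MTHFD1 at 0.023, TYMS at -0.0060 and GART at -0.0020 on the log2 scale. The median of this list was 0.0033 and its mean -0.012, so that these differ in sign. Among the 13 mitochondrial enzymes, 5 lay above 0, with MTHFD1L at 0.019 and the glycine cleavage subunit GCSH at 0.057, and the list had a median of -0.013 and a mean of -0.096. The lowest values of this list belonged to genes with few reads: DMGDH, dimethylglycine dehydrogenase, had 8.49 ± 2.94 and 14.8 ± 8.77 normalized counts and a log2 fold change of -0.59 (-1.74 to 0.55). ALDH1L2 stood at -0.36 (-1.04 to 0.32), the glycine decarboxylase gene GLDC at -0.23 (-1.07 to 0.60), and the cytosolic ALDH1L1 at -0.19 (-0.63 to 0.24). Each was lower in the library labelled high in 3 of 3 pairs. They were named for their low values, so this shared direction is no separate evidence. Changes of this size were neither called nor excluded. Libraries with neighbouring numbers (1 and 2, 3 and 4, 5 and 6, called pairs 1, 2 and 3) resembled each other, and treating these pairs as a block narrowed the intervals without a call over all genes (smallest adjusted p = 0.341, limma with Benjamini-Hochberg adjustment). In that fit the 22 folate genes with a mean of at least 1000 normalized counts had 95% limits between -6.16% and 11.1%. MTR, methionine synthase (chromosome 1, 236958610 to 237067281 in GRCh37), was the 1 folate gene that passed when adjusted over the list alone in the blocked fit (adjusted p = 0.0073 in limma with Benjamini-Hochberg adjustment). It had 6442 ± 262 and 6039 ± 334 normalized counts, a log2 fold change of 0.094 (95% interval 0.042 to 0.15 with the block, -0.050 to 0.24 without it). MTR was higher in the library labelled high in 3 of 3 pairs. It was singled out on these same pair differences, so this is no separate evidence. Without the block it was not called (unadjusted p = 0.169 in limma, the smallest of the folate genes).

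**Figure D1:**
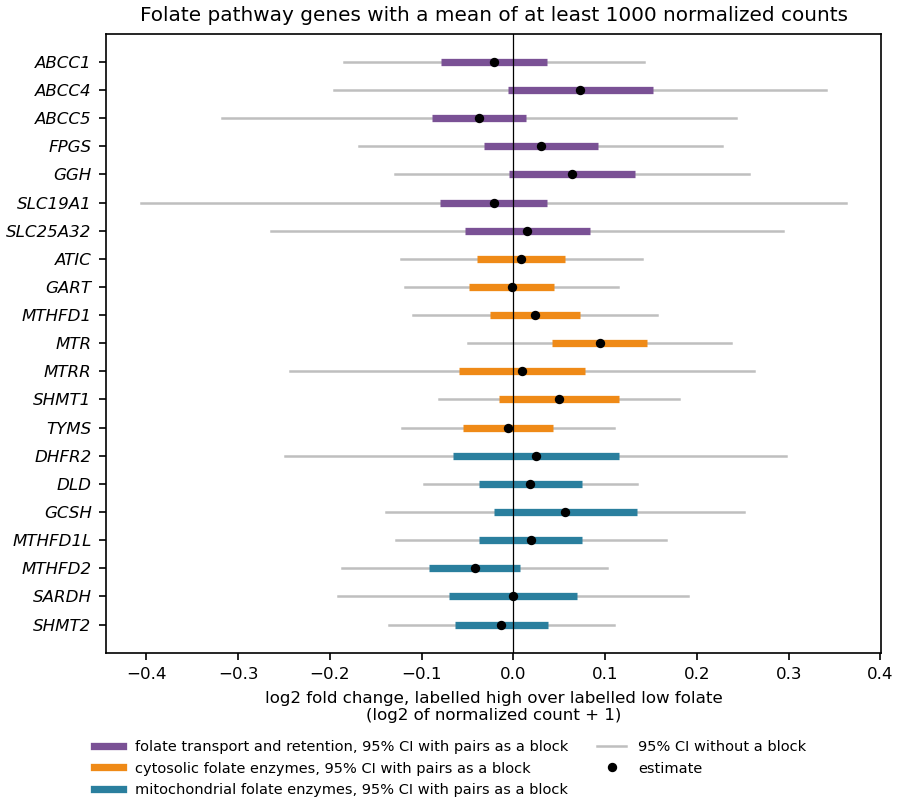
Log2 fold changes, labelled high over labelled low folate, of 21 folate pathway genes with a mean of at least 1000 normalized counts. Points are estimates (3 libraries a group), grey lines 95% intervals of limma without a block and coloured bars those with library pairs as a block; the estimates lie between -0.042 (MTHFD2) and 0.094 (MTR).

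Across all 18008 genes tested, limma called 0 genes between the media at a Benjamini-Hochberg adjusted p under 0.05, with 133 (0.739%) at an unadjusted p under 0.05. Where no gene differs, a well-calibrated test gives a share near 0.05. The fit without a block was therefore conservative, and its 0 calls do not exclude changes. On the recovered reads edgeR also called 0 (104 at an unadjusted p under 0.05), as did limma-voom (116) and DESeq2 (28). The authors' deposited table marks 0 genes as significant, with 94 at an unadjusted p under 0.05 and a smallest adjusted p of 0.9999. Of the 6864 genes with a mean of at least 1000 normalized counts, the largest absolute log2 fold change was 0.245, that of RCBTB2. The groups did not overlap for 653 genes, or 3.63%, where chance gives 10% for 6 exchangeable libraries, but 3.08% to 3.71% in the 3 other splits that part neighbouring library numbers. The median half-width of the 95% interval in these abundant genes was 0.18 on the log2 scale, or 13.2%, before adjustment. In simulated libraries with 1 dispersion for all genes, limma without a block recovered 0% of genes changed 1.2-fold, 26% of those changed 1.5-fold and 48% of those changed 2-fold.

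The main difference between libraries followed their numbers and not the medium. Across 12712 genes, the deviations of libraries 1 and 2 from their group means correlated at r = 0.77, those of 3 and 4 at 0.92 and those of 5 and 6 at 0.87, where genes are not independent replicates. Of 11341 genes with a mean of at least 100 normalized counts, 328 had a range of at least 2-fold over the 3 pair means. Between the means of the 2 media, 1 gene differed at least 2-fold. A range over 3 means is wider by construction than a difference of 2, so these counts are not like for like. The genes named next were chosen after their values were seen. MAGEB1, a cancer-testis antigen gene, had 800 and 782 normalized counts in libraries 1 and 2, 0 and 0.84 in libraries 3 and 4, and 697 and 656 in libraries 5 and 6. PRSS21, a testis serine protease, had 201, 240, 0, 0.84, 197 and 203 normalized counts in libraries 1 to 6. FTCD, a folate-dependent enzyme of histidine breakdown and a member of the cytosolic list, was likewise low in libraries 3 and 4 (8.33 and 9.26 normalized counts) and at 161 to 209 in the other 4. CD34, a progenitor cell marker, and CBS, the first enzyme of transsulfuration, were instead at their highest in that pair, with pair means of 78.7, 421 and 57.2 normalized counts for CD34 and 41.1, 221 and 38.7 for CBS. NKX2-5, TAL1 and LMO2, transcription factors of T-cell leukaemia, had pair means within 1.27, 1.28 and 1.42-fold of each other.

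**Figure D2:**
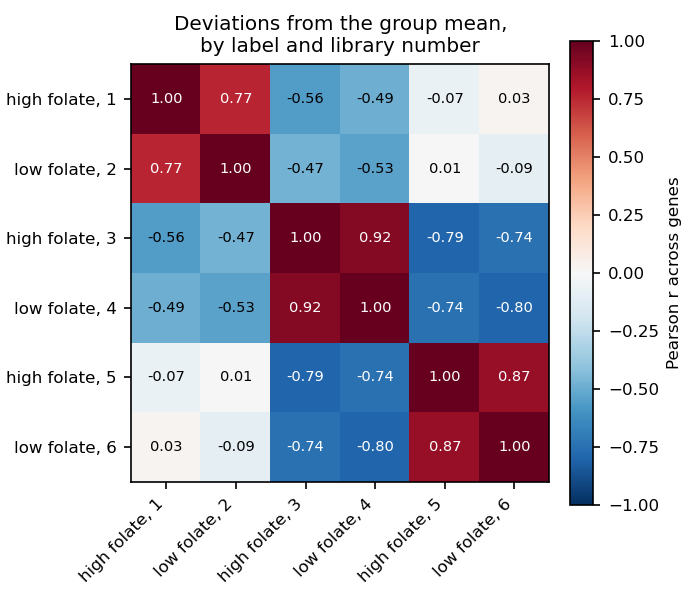
Pearson correlations, across 12712 genes, between the 6 libraries' deviations from their group means, by label and library number (both axes). Libraries of consecutive number correlate at 0.77, 0.92 and 0.87, and all other pairs of libraries from different groups at 0.030 or below. Deviations sum to 0 within a group, so a high correlation with 1 library of the other group forces the remaining ones down on average.

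**Figure D3:**
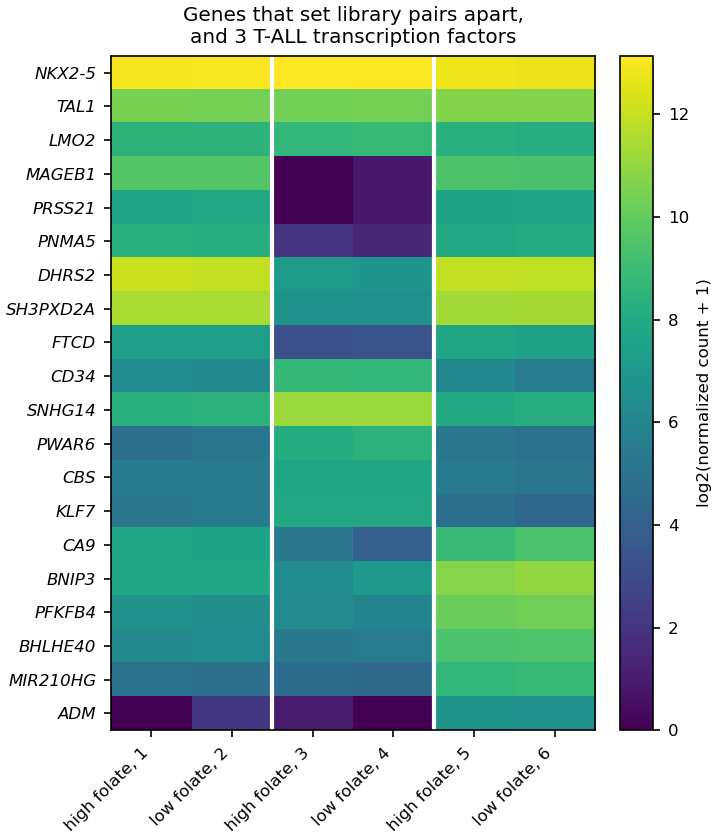
Log2 of the normalized count plus 1 (colour) of 20 genes (vertical axis) in the 6 libraries (horizontal axis), chosen after their values were seen, with white lines between library pairs. MAGEB1 falls to 0 and 0.84 normalized counts in libraries 3 and 4, and BNIP3 reaches 1700 and 2081 in libraries 5 and 6.

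With the pairs as a block, a choice made after the data were seen, 8 genes were called by limma, 2 higher and 6 lower in the libraries labelled high, at Benjamini-Hochberg adjusted p-values of 0.0062 to 0.0246. RCBTB2 (chromosome 13, 49063095 to 49107369 in GRCh37) fell from 1332 ± 115 to 1122 ± 63.4 normalized counts, a log2 fold change of -0.24 (blocked 95% interval -0.33 to -0.16). IFITM2, an interferon-induced membrane protein gene, was lower by a log2 fold change of -0.17 (-0.24 to -0.11), and DUSP6, a phosphatase of ERK, by -0.20 (-0.28 to -0.12). The other genes called lower were the chitinase-like gene CHI3L2 at -0.14, ARHGAP29 at -0.30 and ANXA1, which encodes annexin A1, at -0.14. RBM3, a cold-inducible RNA-binding protein gene (chromosome X, 48432837 to 48437454), was higher, with 10650 ± 1683 against 9683 ± 1096 normalized counts and a log2 fold change of 0.13 (0.082 to 0.18). SNORD3A, the U3 small nucleolar RNA (chromosome 17, 19091329 to 19092027), was the only one of the 8 to change at least 2-fold, with 29.2 ± 14.9 against 7.56 ± 1.56 normalized counts and a log2 fold change of 1.73 (1.1 to 2.36); it belongs to a family of near-identical copies, so that its count is uncertain. All 8 kept 1 direction in 3 of 3 pairs, but they were called on these same pair differences, so this is no separate evidence. The blocked intervals rest mostly on spread pooled over genes and can understate a gene's own. DUSP6, for example, had differences of -0.042, -0.26 and -0.31 in pairs 1, 2 and 3. DESeq2 with the same block called 0 genes (104 at an unadjusted p under 0.05), and another split of the libraries that also parts every pair gave 15 called genes in limma. At an unadjusted p under 0.05, limma with the block had 1221 genes (6.78%). The other splits that part every pair had 619, 763 and 1291. Without pair 1, 18 genes were called and SNORD3A was lost; without pair 2, 6 were called and IFITM2, RBM3, DUSP6 and RCBTB2 were lost; without pair 3, 32 were called and ANXA1, CHI3L2, DUSP6 and ARHGAP29 were lost.

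**Figure D4:**
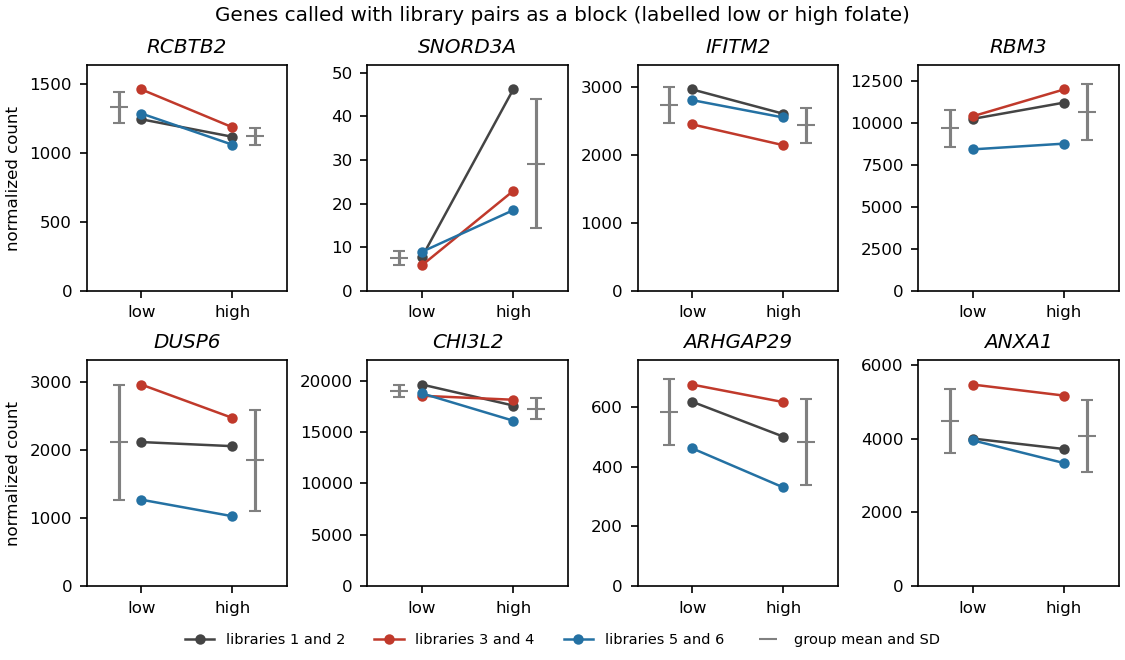
Normalized counts (vertical axes, from 0) of the 8 genes called with library pairs as a block, in libraries labelled low and high folate. Lines join the libraries of a pair, and grey bars give each group's mean and SD (n = 3); SNORD3A has 18.5 to 46.2 normalized counts in the high and 5.89 to 8.97 in the low libraries.

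Of the 23 gene lists with at least 3 tested members, limma's camera called 0 between the media without a block (smallest Benjamini-Hochberg adjusted p = 0.142, for ribosome biogenesis and MYC targets). With the block it called 4. Ribosome biogenesis and MYC targets were higher in the libraries labelled high, with a median log2 fold change of 0.048 and 19 of 22 genes above 0 (camera adjusted p = 2.2e-07, and adjusted p = 0.599 with an estimated correlation). Of these, 0 passed over all genes and 7 passed when adjusted over the list alone, among them NOP58 at 0.086, the rRNA methyltransferase gene FBL at 0.094 and nucleolin, NCL, at 0.051. The DNA replication genes were also higher, by a median of 0.015 with 29 of 35 above 0 (camera adjusted p = 0.0210, and 0.599 with an estimated correlation), and 0 of them passed when adjusted over the list alone. T lineage markers were lower, by a median of -0.030 with 10 of 31 above 0 (camera adjusted p = 0.0082, and 0.599 with an estimated correlation); CD7 at -0.13 and CD1E at -0.17 passed when adjusted over the list alone, and 0 over all genes. ATF4 targets, genes of the amino acid and stress response, were lower by a median of -0.018 with 7 of 28 above 0 (camera adjusted p = 0.0210, and 0.745 with an estimated correlation). Their medians in pairs 1, 2 and 3 were -0.034, -0.033 and 0.018, so the direction turned in pair 3. None of the 4 calls held with an estimated correlation or in fry (smallest adjusted p = 0.209), and the other splits that part every pair gave 3 to 5 called lists. Leaving out pair 1, 2 or 3 gave 5, 3 and 7 called lists with the block, and leaving out each of the 6 libraries in turn gave 1 to 4 without it. These totals do not mean that the same lists were kept: the DNA replication list was not called without pair 1, 2 or 3.

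The remaining lists were not called in either fit of all 6 libraries, though some of them were called with the block when a pair was left out. Purine synthesis had a median log2 fold change of 0.0085 (10 of 15 genes above 0), pyrimidine and deoxynucleotide synthesis 0.0052 (12 of 20), and serine synthesis and transport -0.015 (5 of 12). The methionine cycle and transsulfuration list had a median of 0.0046 (10 of 17), and MTR, which it shares, passed when adjusted over this list alone in the blocked fit. The folate transport, cytosolic and mitochondrial lists had camera adjusted p-values of 0.566, 0.566 and 0.420 with the block. Mitochondrially encoded transcripts had a median of 0.0011, in which medians of -0.051, -0.024 and 0.088 in pairs 1, 2 and 3 cancelled. The nuclear-encoded respiratory chain subunits had a median of 0.0073. The mitosis list stood at 0.016, cholesterol synthesis at 0.029, glycolysis and hypoxia response at -0.013, p53 targets at -0.0035, interferon response at -0.039 and NOTCH targets at 0.0028. The mitosis, cholesterol and glycolysis lists had medians above 0 in pairs 1 and 2 and below 0 in pair 3. Immediate early genes had a median of 0.013, and EGR1 alone passed when adjusted over the list in the blocked fit, with 24.0 ± 21.1 against 10.5 ± 7.42 normalized counts in 2 of 3 pairs. Of the markers of other cell types, 7 B cell, 6 myeloid and 5 fibroblast and epithelial genes were tested, with medians of -0.0084, 0.17 and -0.0074, and the erythroid list had 1 tested gene at -0.038. The mean of the folate transport, p53 and B cell lists, and camera's direction, had the opposite sign to their median, and camera's direction for NOTCH targets turned downward with the block.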

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

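No paired analysis by the labels' replicate numbers was possible because the columns carry none, and all settings with a block were added after seeing the data, with pairs given by library number. Without a block, every setting run called 0 genes, namely limma with pseudocounts of 0.1 and 10 (133 and 140 genes at an unadjusted p under 0.05), limma without a filter (518), edgeR with TMM, RLE or upper-quartile scaling (104, 103 and 104), edgeR without a filter (354) or with at least 10 reads in 3 libraries (109), limma-voom (116), DESeq2 (28) and each library left out (101 to 216). With the replicate block limma called 8 genes (2 higher, 6 lower, 1 at least 2-fold), with the same counts at pseudocounts of 0.1 and 10. EdgeR called 16 (8 higher, 8 lower, 2 at least 2-fold), limma-voom 12 (4 higher, 8 lower, 2 at least 2-fold) and limma without a filter 24 (16 higher, 8 lower, 5 at least 2-fold), and all 3 kept the 8 genes. DESeq2 with the block called 0 (104 at an unadjusted p under 0.05), and the cause was not tested. At that unadjusted threshold the block gave 1221 genes in limma, 1203 in edgeR and 1165 in limma-voom. Without pair 1, limma called 18 (9 higher, 9 lower, 2 at least 2-fold, sharing 7 of the 8), without pair 2, 6 (2 higher, 4 lower, 1 at least 2-fold, sharing 4), and without pair 3, 32 (25 higher, 7 lower, 13 at least 2-fold, sharing 4); fewer libraries remain in each, and the cause of the larger counts was not tested. Gene lists called numbered 0 without a block, also without a filter, with an estimated correlation and in fry, but 1 to 4 when 1 library was left out, which leaves a pair without its partner. With the block they numbered 4, without a filter 3, and 5, 3 and 7 without pairs 1, 2 and 3, but these were not all the same lists. With an estimated correlation or fry they numbered 0. The block changed no call among the folate genes over all genes. The scalings moved the median of all genes by at most 0.0014 on the log2 scale. In genes with a mean of at least 1000 normalized counts the median 95% half-width was 13.2% without and 4.61% with the block, before adjustment. At the adjusted threshold, changes of 1.2-fold simulated with 1 dispersion for all genes were recovered for 0% of genes without the block and 57.1% with it.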

Other observations

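Of the tests in this part, the depth ratio, both counts of splits and the per-pair test of non-polyadenylated RNAs were chosen after the results they bear on were seen. The libraries numbered 5 and 6, from both media, had the highest levels of glycolysis and hypoxia genes. The list's median deviation from the gene means was 0.35 in that pair on the log2 scale, against -0.15 in libraries 1 and 2 and -0.21 in libraries 3 and 4. BNIP3, a mitophagy receptor induced by low oxygen, had pair means of 231, 107 and 1891 normalized counts, and CA9, carbonic anhydrase 9, of 209, 25.8 and 581. PFKFB4 stood at 98.4, 69.9 and 1183, the lactate exporter gene SLC16A3 at 893, 335 and 1837, and MIR210HG, the host transcript of a hypoxia-induced microRNA, at 28.4, 23.3 and 429. Cholesterol synthesis genes were also highest in that pair (median deviations of -0.064, -0.19 and 0.22), and ribosome biogenesis and MYC targets lowest (0.13, 0.051 and -0.20). These genes were picked after their values were seen, and pairs were not tested against each other.

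Libraries 3 and 4 differed from the other 4 by genes that were far lower or higher in them. With a mean of at least 100 normalized counts in both other pairs, 9 genes were over 10-fold lower there, among them DHRS2 (pair means of 4144, 129 and 3858), SH3PXD2A (2861, 101 and 2598) and PNMA5 (302, 2.40 and 264). In the other pairs 0 genes met that rule, while 4 genes were over 10-fold higher in libraries 3 and 4 and 6 in libraries 5 and 6. SNHG14 and PWAR6, noncoding transcripts of the imprinted region of chromosome 15 (25223730 to 25664609 and 25277020 to 25281637 in GRCh37), had pair means of 337, 2286 and 276, and of 31.2, 313 and 32.1 normalized counts. The cardiac homeobox gene NKX2-5 was abundant in all 6 libraries, with 6969 to 9028 normalized counts.

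The resemblance of libraries with consecutive numbers stayed after a correction for GC content and gene length (smallest pair correlation 0.773) and in genes with a mean of at least 1000 normalized counts (0.858), and total reads differed by up to 1.23-fold within a pair, which argues against these as the cause. Another cell line in 1 pair is argued against by NKX2-5, which a translocation drives in CCRF-CEM and whose pair means lay within 1.27-fold. Cells of another type are argued against, though narrowly, by marker lists that deviated by at most 0.458, under but near the bound set in advance. That value came from 6 myeloid genes in libraries 5 and 6, where the T lineage list was at -0.13, as this explanation also required. CD14 reached no more than 7.57 normalized counts in any library, LYZ 3.37 and S100A8 0. For libraries 5 and 6, a candidate explanation is lower oxygen or denser cultures: 21 other targets of hypoxia-inducible factors, listed before their own values were seen but after the hypoxia list was seen to be high in that pair, had a median deviation of 0.365 there (95% bootstrap interval 0.23 to 0.53; 21 of 21 above 0), against -0.12 and -0.23 in the other pairs. That interval came from a bootstrap over genes and does not measure the spread between libraries. As deviations were taken from each gene's mean over all 6 libraries, a high pair lowers the others, which are no independent contrast. What sets libraries 3 and 4 apart stays open, and no biological explanation given by the design was tested for it.

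SNORD3A was higher in the libraries labelled high in all 3 pairs, by 2.42, 1.80 and 0.97 on the log2 scale. Less complete poly(A) selection in those libraries is left undecided by 193 other genes classed by name or type as non-polyadenylated RNAs. Their median log2 fold change was -0.017 (-0.051 to 0.023), under the bound set against it in advance. Pseudogene copies were not removed from that class. It also holds intronic small nucleolar RNAs, which carry-over could affect less than a free-standing RNA. The median therefore shows only that the class as a whole did not rise. More cells in S phase are left undecided, as the bounds set in advance for and against them were both met. Against them, the DNA replication genes' median log2 fold change had an upper limit of 0.029, under the 0.05 set in advance. That limit came from a bootstrap over genes and does not measure the spread between libraries. What more S phase was expected in advance to show was also met in the blocked fit, but less firmly, and HIST1H1B, 1 of the histone genes, had by then been seen to be higher. The DNA replication list was called higher there (camera adjusted p = 0.0210), but not with an estimated correlation (adjusted p = 0.599), in fry (0.209) or in camera without pair 1, 2 or 3 (0.065, 0.085 and 0.053), all with Benjamini-Hochberg adjustment in limma. Histone genes had a median of 0.28 (0.15 to 0.44), with medians of 0.57, 0.37 and -0.097 in pairs 1, 2 and 3. This is the same order of pairs as in the 5 free-standing RNAs named below. Carry-over and S phase are therefore not told apart by the histone genes, and what raised them in pairs 1 and 2 stays open. Carry-over in pairs 1 and 2 remains possible, and could act on free-standing RNAs more than on the intronic small nucleolar RNAs in that class: RNU4-2, RPPH1, RN7SL1, RN7SL2 and RN7SK had a median difference of 1.95 in libraries 1 and 2 and 1.71 in 3 and 4, but -0.73 in 5 and 6, where SNORD3A was still higher; these 5 had already been seen to rise without pair 3, so the test decides nothing.

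The 8 genes called with the block, RBM3 among them, were set against other splits of the libraries. In the fit without a block, 10 of the 10 splits of the 6 libraries gave as many called genes as the real one, as all called 0 (highest of the others 0), though splits that keep library pairs together had up to 3237 genes at an unadjusted p under 0.05, which points to the pair structure. Among the 4 splits that part every pair, 2 gave as many blocked calls as the real 8, the highest other being 15 with libraries 1, 3 and 6 against the rest; 10 or 4 splits are too few for a share under 0.05. Cooler handling of the libraries labelled high, a candidate explanation for RBM3, is left undecided by CIRBP, the other cold-inducible gene: its log2 fold change was 0.052 (0.0031 to 0.10), above 0 and yet below the 0.13 of RBM3, and the bound set against it was a poor one, since nothing requires both genes to respond equally. Across 6864 abundant genes the high-minus-low differences correlated at 0.23 between pairs 1 and 2, -0.069 between pairs 1 and 3 and 0.038 between pairs 2 and 3, where genes are not independent replicates.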
